A study of Homo sapiens with 15 samples.

How the data were processed

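RNA was measured by sequencing in 15 libraries of Caco-2 cells, a human colorectal adenocarcinoma line that forms an enterocyte-like layer when it is left to differentiate. Per the labels' protocols, cells were grown on membranes for 14 days with retinoic acid. Exposure was for 24 h to 5-fluorouracil (5-FU, 50 µg/ml), an antimetabolite that inhibits thymidylate synthase and is incorporated into RNA, or the cells were left unexposed. They were then washed, and bacterial components were added for 72 h. Stranded mRNA libraries were made from 200 ng of total RNA and read as 150-base paired ends. Samples were grouped by their titles into 5 groups of 3 libraries: Chem, 5_FU, 5_FU_plus_LR, 5_FU_plus_EPS and 5_FU_plus_MV. The group titled Chem is called a negative control in the header of the count table and is read here as the unexposed cells, although the labels do not state this outright. EPS is read as exopolysaccharides from the series title, and LR and MV are not spelled out in the labels. The labels do not state that the replicates, numbered 2, 3 and 4, come from separate cultures, so p-values measure the spread between these samples, which may be technical.

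The deposited values are whole-number counts per gene, not normalised. The submitters' processing notes name STAR, featureCounts, DESeq2, R 4.3.3 and the GRCh38 genome, and the labels' protocols name bcl2fastq 2.20.0. The annotation release and the strand setting of the counting are not given in the sources used here. Reads of overlapping genes and of antisense genes are therefore uncertain, as are those of near-identical copies such as SAA1 and SAA2. The table listed 63140 gene identifiers, of which 62541 were matched to a symbol table and 599 were not. Gene positions are those of the GRCh38 reference annotation.

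From these counts, edgeR 4.0.16 in R 4.3.3 was run with TMM scaling, its default filter on low counts (filterByExpr, minimum count 10) and its quasi-likelihood F test. All 15 libraries entered 1 fit with group as the only term, which left 10 residual degrees of freedom, and 18065 genes were tested. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Each log2 fold change is given with its standard error (SE), taken as its size divided by the square root of F. Levels are TMM-scaled CPM, given as mean ± SD over 3 libraries. The comparison of Chem with 5_FU was fitted as Chem minus 5_FU and is reported with the sign turned, as 5_FU minus Chem.

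For gene groups, 37 lists were fixed, of which 36 had at least 5 tested members. They were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Calls that hold with an estimated correlation were counted beside them. Fry in limma, which asks whether the members change at all rather than more than other genes, was set beside camera. Its FDR is given for some lists only. Members are counted by their adjusted p over all genes tested and, separately, adjusted over the list alone. The groups, tests, lists, alternatives and the rule for naming genes were set before the data were examined. The rule names, in each direction, the 6 called genes with the largest changes (3 between component groups) and the 5 with the smallest p, with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups. It also takes up to 3 called members of each list (or the member with the smallest p where a described list has none), and a panel of 20 barrier, proliferation, p53 and inflammation genes, of which 19 were tested. Where fewer than 5 genes were called, all are named. The text gives only some of the genes that the rule names.

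The alternatives were RLE size factors, no filter on low counts, a replicate block, a test against a 1.5-fold change (glmTreat), a fit of only the 6 libraries compared (4 residual degrees of freedom), limma-voom, DESeq2 1.42.0, and leaving out each library in turn. Scaling by library size only, and leaving out all libraries of number 2, were added after the data were seen. Whether the shared replicate numbers pair the libraries was checked by correlating the deviations of same-numbered libraries from their group means. Of 30 such pairs, 19 had a correlation over 0.1 (range 0.0106 to 0.376), and 24 correlated best with their own number. Every pair was over 0.1 for 5_FU with 5_FU_plus_LR, 5_FU with 5_FU_plus_EPS, and 5_FU_plus_LR with 5_FU_plus_EPS, so the blocked result stands beside those comparisons.

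The procedure was tested on simulated counts for 5_FU_plus_EPS against 5_FU, with 17485 genes. It recovered 23 of 67 genes changed 1.5-fold (34.3%), 51 of 67 changed 2-fold (76.1%) and 61 of 66 changed 4-fold (92.4%), with 5 false calls among 140. A simulated list of 25 genes shifted 1.25-fold reached a camera adjusted p of 3.93e-31, and 0 of 36 unchanged lists were called by camera among 17503 genes. The simulated genes were drawn independently of each other. These runs therefore cannot tell how camera behaves where the genes of a list vary together. In the data the estimated correlation was, for example, 0.792 for cytosolic ribosomal proteins in Chem against 5_FU. Total counts ranged from 22127937 to 36185882 per library, so a gene at 1 CPM rests on 22.1 to 36.2 reads in a library. The figures were drawn with matplotlib. No gene of the Y chromosome and no gene without a symbol is named.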

Results

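The 15 libraries, 3 in each of 5 groups of Caco-2 cells, held 22127937 to 36185882 counts each, and no pair of groups differed in depth at an exact permutation p under 0.3. Within groups, the log CPM of replicate pairs correlated across genes at 0.989 to 0.994, and a chi-square per degree of freedom of 3.38 to 21.2 put every pair beyond sampling noise. The first principal component took 50.1% of the variance and separated Chem, at 63.1 to 67.6, from 5_FU, at -22.2 to -18.8. The 5_FU_plus_EPS libraries lay between, at -5.14 to -1.06, while those of 5_FU_plus_LR and 5_FU_plus_MV lay from -22.1 to -17.6. The second component took 10.7% of the variance and was highest in the library of number 2 in every group, led by 5_FU replicate 2 at 38.9.

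**Figure D1:**
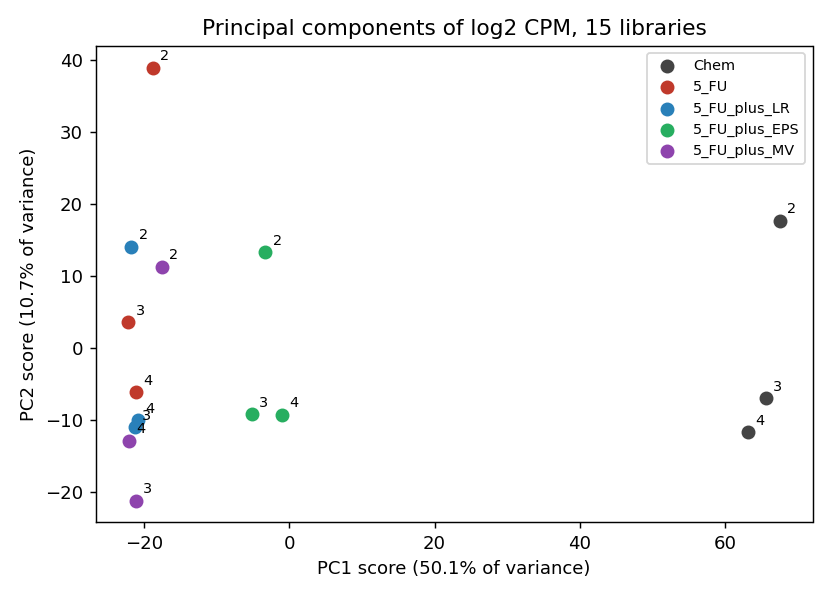
Scores of the 15 libraries on the first 2 principal components of log2 CPM, with the share of variance on each axis, coloured by group and marked with the replicate number. Chem lies at 63.1 to 67.6 on the first component, 5_FU_plus_EPS at -5.14 to -1.06 and the other groups below -17.5, and 5_FU replicate 2 stands highest on the second.

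The comparison of 5_FU with Chem asked what exposure to 5-FU left in the cells at the end of the culture. Among genes of at least 5 CPM in the higher group, the largest fall in 5_FU was that of ANO1, a calcium-activated chloride channel, from 24.6 ± 3.17 to 0.766 ± 0.123 CPM (SD, n = 3), a log2 fold change of -5.02 ± 0.23 (SE; edgeR adjusted p = 8.15e-11). LHPP, a phosphatase, followed at -3.47 ± 0.12 and the placental galectin gene LGALS14 at -3.33. The largest rise under the same condition was that of SLC13A2, a dicarboxylate transporter, from 0.537 ± 0.208 to 9.56 ± 1.504 CPM (SD, n = 3), a log2 fold change of 4.17 ± 0.25 (SE; edgeR adjusted p = 1.28e-09). The non-coding LINC02936 (3.16), the lectin gene REG4 (2.86) and the acute-phase gene SAA1 (2.56) were next. Both are protein-coding genes: ANO1 (ENSG00000131620) lies on chromosome 11 from 70078302 to 70189528 of GRCh38, and SLC13A2 (ENSG00000007216) on chromosome 17 from 28473293 to 28497781. The smallest p-values among falls belonged to LHPP, to PCK2, a mitochondrial gluconeogenic enzyme (-1.96 ± 0.07), and to catalase, CAT (-1.75 ± 0.07).

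The 32 cytosolic ribosomal protein mRNAs were all lower in 5_FU, 32 also when adjusted over the list alone, with a median log2 fold change of -0.85 (camera adjusted p = 1.12e-39; adjusted p = 0.146 with an estimated correlation). RPL3 fell from 1532 ± 31.9 to 594.8 ± 44.9 CPM and RPL10A from 622.0 ± 11.3 to 178.8 ± 17.3 CPM (SD, n = 3). These genes have many processed pseudogenes, so the level of a single member is uncertain, and the summed CPM of 1601 such pseudogenes fell from 511.6 ± 18.8 to 321.5 ± 18.7 (SD, n = 3). Genes of ribosome biogenesis went the other way, with 19 of 26 higher and 3 lower (19 and 4 adjusted over the list alone; camera adjusted p = 0.0019, and adjusted p = 0.62 with an estimated correlation). Among them were NOLC1 (0.58 ± 0.06) and DKC1 (0.53 ± 0.07), nucleolar factors of small nucleolar ribonucleoproteins.

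Of 22 genes of cholesterol biosynthesis, 21 were lower and 0 higher in 5_FU by edgeR (21 and 1 adjusted over the list alone), among them ACAT2 (-1.02 ± 0.05), NSDHL (-1.02 ± 0.07) and INSIG1 (-0.85 ± 0.06). Over all genes, 10574 had an unadjusted p under 0.05, and limma-voom and DESeq2 called 9661 and 9291. The camera adjusted p of this list was 1.05e-10, and its adjusted p = 0.146 with an estimated correlation. Of 24 genes of the unfolded protein and integrated stress response, 16 were lower and 2 higher (17 and 2 adjusted over the list alone), including the chaperones CALR (-0.93 ± 0.07), PDIA4 (-0.94 ± 0.05) and HSPA5 (-0.74 ± 0.06). Its camera adjusted p was 2.79e-05, and its adjusted p = 0.146 with an estimated correlation. In the hypoxia and glycolysis list, 15 of 26 were lower and 2 higher (15 and 2 adjusted over the list alone), led by PDK1, which restrains pyruvate oxidation (-2.52 ± 0.31), and hexokinase HK1 (-1.64 ± 0.18). Its camera adjusted p was 0.00594, and its adjusted p = 0.62 with an estimated correlation. Replication-dependent histone genes were lower in 9 of 17 (9 adjusted over the list alone), such as H1-2 (-1.46 ± 0.11) and H2AC8 (-1.57 ± 0.17), whose levels are uncertain because histone genes are near-identical copies. Camera gave them an adjusted p of 0.0227, and their adjusted p = 0.272 with an estimated correlation.

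Chemokine and NF-kB response genes were higher in 17 of 27 and lower in 2 (17 and 2 adjusted over the list alone), including CCL20, a chemokine for dendritic cells and lymphocytes (1.82 ± 0.18), SAA1 (2.56 ± 0.26) and NFKBIZ (0.74 ± 0.06). This list had a camera adjusted p of 0.000472, and its adjusted p = 0.255 with an estimated correlation. S phase and replication genes were higher in 16 of 31 and lower in 2 (16 and 2 adjusted over the list alone), among them ORC6 (0.87 ± 0.09) and RFC4 (0.78 ± 0.08). For this list the camera adjusted p was 0.00748, and the adjusted p = 0.757 with an estimated correlation. DNA repair genes were higher in 17 of 28 and lower in 2 (17 and 2 adjusted over the list alone), including XRCC2, of homologous recombination (1.17 ± 0.09), and the checkpoint kinase CHEK1 (0.77 ± 0.10). Camera gave an adjusted p of 0.0111, and the adjusted p = 0.628 with an estimated correlation. Apoptosis regulators were higher in 12 of 24 (12 adjusted over the list alone), and those with the smallest p were the anti-apoptotic BCL2L1 (0.75 ± 0.08) and CFLAR (0.37 ± 0.06). Their camera adjusted p was 0.023, and their adjusted p = 0.567 with an estimated correlation.

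Barrier and differentiation genes went in mixed directions. Of 24 tight junction genes, 10 were higher and 6 lower in 5_FU (10 and 6 adjusted over the list alone), and the list was not called (camera adjusted p = 0.514; adjusted p = 0.839 with an estimated correlation). Its median of 0.02 and its mean of -0.02 had opposite signs, and camera gave its direction as up. Occludin, OCLN, rose by 0.67 ± 0.05 from 111.5 ± 4.65 CPM, and claudin genes CLDN1 and CLDN2 by 0.37 ± 0.08 and 0.72 ± 0.12, while the myosin kinase MYLK fell by 0.79 ± 0.09. CLDN4 (log2 fold change -0.08 ± 0.08, edgeR adjusted p = 0.406) and E-cadherin, CDH1 (-0.04 ± 0.06, edgeR adjusted p = 0.571), did not pass, and the sign of CDH1 turned with scaling by library size only. Brush border and enterocyte genes were lower in 14 of 33 and higher in 4 (14 and 4 adjusted over the list alone), including APOA4 (-2.20 ± 0.19), APOB (-0.77 ± 0.08) and villin, VIL1 (-0.56 ± 0.06). That list was not called (camera adjusted p = 0.0507; adjusted p = 0.628 with an estimated correlation), nor was that of intestinal stem cell and WNT target genes, with 10 of 21 higher and 2 lower (10 and 2 adjusted over the list alone; camera adjusted p = 0.0534). MYC (1.16 ± 0.12), LRIG1 (0.64 ± 0.05) and RNF43 (0.64 ± 0.08) were among its rises. Unlike camera, fry passed these lists, with an FDR of 0.00931 for tight junctions, 0.00154 for brush border genes and 0.00234 for stem cell and WNT target genes.

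Genes of the p53 response were split, with 9 of 24 higher and 5 lower (9 and 6 adjusted over the list alone; camera adjusted p = 0.888). The list's median log2 fold change of -0.06 and its mean of 0.03 had opposite signs, and camera gave its direction as up. GDF15, a stress cytokine, rose by 1.61 ± 0.19, whereas CDKN1A, the p21 cell cycle inhibitor, fell by 1.18 ± 0.16 and CCNG1 by 1.245 ± 0.14. The proliferation marker MKI67 rose by 0.63 ± 0.11. The target of 5-FU, TYMS, stood at 72.3 ± 4.06 CPM in Chem and 91.2 ± 10.9 CPM in 5_FU (SD, n = 3) and did not pass (edgeR adjusted p = 0.0806). Of 14 alternatives, 5 called it, with adjusted p values of 5.63e-05 by edgeR without a filter on low counts, 0.000861 with the replicate block, 0.0103 in a fit of the 6 libraries alone, 0.0416 with scaling by library size only and 0.000213 without the libraries of number 2, while the highest was 0.287, without 5_FU replicate 3. TYMP, thymidine phosphorylase, rose by 1.85 ± 0.19.

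In all, edgeR called 9676 of 18065 tested genes (53.6%), 4923 higher and 4753 lower in 5_FU, of which 943 and 1289 changed over 2-fold. With scaling by library size only the split was 5672 higher and 4153 lower in 5_FU. Of the 19 panel genes tested, 14 passed. A test against a 1.5-fold change called 2077 genes. Markers of other cell types moved in part: Paneth and tuft cell markers were higher in 4 of 7 and enteroendocrine markers in 4 of 5 (camera adjusted p = 0.0833 and 0.194). Goblet cell markers were higher in 3 and lower in 3 of 9, leukocyte markers in 2 and 2 of 8, and fibroblast markers in 1 and 1 of 6. Goblet cell markers had a median of -0.06 and a mean of 0.48, with camera's direction up, and fibroblast markers a median of -0.02, whose sign turned with scaling by library size only, and a mean of 0.14, with camera's direction up.

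Exposed cells that then received the component titled LR were compared with exposed cells that received none. SAA1 rose from 5.40 ± 0.211 to 12.9 ± 2.13 CPM (SD, n = 3), a log2 fold change of 1.252 ± 0.19 (SE; edgeR adjusted p = 0.0331), and CCL20 from 5.04 ± 0.874 to 9.61 ± 0.969 CPM, at 0.92 ± 0.15 (SE; edgeR adjusted p = 0.0425). The other called genes were SAA2, a near-identical copy of SAA1, so that the level of each is uncertain (1.49 ± 0.20), LCN2, which encodes an iron-sequestering antibacterial protein (1.92 ± 0.31), and CYP24A1, the vitamin D 24-hydroxylase (3.47 ± 0.47). CYP24A1, which is outside the naming rule and was chosen after its values were seen, rests on few reads, with 7 counts over the 5_FU libraries and 90 over the 5_FU_plus_LR libraries. Of the protein-coding genes SAA1 (ENSG00000173432) and CCL20 (ENSG00000115009), SAA1 lies on chromosome 11 from 18266174 to 18269977 and CCL20 on chromosome 2 from 227805739 to 227817564.

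These 5 genes, all higher, were the calls of edgeR (0 lower), while 1218 genes had an unadjusted p under 0.05. Limma-voom called 3 and DESeq2 8, and the replicate block called 43, with 22 higher and 21 lower. Leaving out 5_FU replicate 2, 3 or 4 or 5_FU_plus_LR replicate 3 gave 0 calls, and leaving out 5_FU_plus_LR replicate 2 or 4 left 1 gene, CYP24A1. With 1 library left out, the edgeR adjusted p of CYP24A1 was 0.0561 to 0.115 where it was lost, and those of the other genes were 0.0522 to 0.275 with each of the 6 libraries left out. A fit of the 6 libraries alone called 2, SAA1 and SAA2, and a test against a 1.5-fold change called 0.

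The list of chemokine and NF-kB response genes rose, with 4 of 27 called and 0 lower by edgeR (13 and 0 adjusted over the list alone), and a median log2 fold change of 0.21, and with the replicate block 8 were called higher. Its camera adjusted p was 5.43e-24, and it was the 1 list still called with an estimated correlation (adjusted p = 0.00285). TNFAIP3, an inhibitor of NF-kB signalling, was 55.8 ± 2.59 CPM in 5_FU and 75.5 ± 8.47 CPM in 5_FU_plus_LR (SD, n = 3; edgeR adjusted p = 0.15, and 0.0007 with the replicate block). Camera called 11 lists. MHC class I genes (median 0.12) had a camera adjusted p of 0.000578 with 0 of 15 members called by edgeR (2 higher adjusted over the list alone; adjusted p = 0.51 with an estimated correlation). Interferon response genes (median 0.11) had a camera adjusted p of 0.00148 with 0 of 30 called by edgeR (1 higher adjusted over the list alone; adjusted p = 0.484 with an estimated correlation). By fry neither passed, with an FDR of 0.422 for MHC class I and 0.288 for interferon response genes. The interferon gene with the smallest p was CXCL10 (1.14 ± 0.25; edgeR adjusted p = 0.373, and 0.0237 with the replicate block). Mitochondrial genome mRNAs were among the called lists, at a median of -0.175 (camera adjusted p = 0.00569, and 0.622 with an estimated correlation). Their share of counts was lowest of all 15 libraries in 5_FU_plus_LR replicate 3, at 2.90%. Without 5_FU replicate 2 the number of lists called was 7, and without 5_FU_plus_LR replicate 3 it was 3. Of the 19 panel genes tested, CCL20 alone passed, and the values of OCLN (-0.03 ± 0.05; edgeR adjusted p = 0.888) and CLDN1 (-0.03 ± 0.07; edgeR adjusted p = 0.919) turned sign without 5_FU_plus_LR replicate 2 (0.00796 and 0.021), that of CLDN1 also without 5_FU replicate 4 (0.00226).

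The comparison of 5_FU_plus_EPS with 5_FU asked what exopolysaccharides added after 5-FU changed. With at least 5 CPM in the higher group, the largest rise was LGALS14, at 2.02 ± 0.43, followed by DDIT4, a stress-induced inhibitor of mTORC1, from 8.68 ± 0.648 to 24.5 ± 1.66 CPM (SD, n = 3), at 1.495 ± 0.19 (SE; edgeR adjusted p = 0.00114). The collagen gene COL5A1 (1.28 ± 0.27), the cystine transporter SLC7A11 (1.23 ± 0.22) and the disulfide-forming oxidase QSOX1 (1.23 ± 0.16) came next. The largest falls at that level were SLC13A2, from 9.56 ± 1.504 to 3.61 ± 0.765 CPM (SD, n = 3), at -1.42 ± 0.19 (SE; edgeR adjusted p = 0.00115), REG4 (-1.32 ± 0.30), CEACAM5 (-1.11 ± 0.21), GDF15 (-1.05 ± 0.18) and the superoxide-generating oxidase NOX1 (-1.02 ± 0.16). Below that level, CYP24A1, chosen after its values were seen, rose by 2.98 ± 0.50 (edgeR adjusted p = 0.00538) on 57 counts over the 5_FU_plus_EPS libraries against 7 over those of 5_FU. DDIT4 (ENSG00000168209), a protein-coding gene, lies on chromosome 10 from 72273920 to 72276036. Among the smallest p-values were those of the peptidase LAP3 (0.81 ± 0.08; edgeR adjusted p = 0.000566) and LHPP (1.01 ± 0.12; edgeR adjusted p = 0.000867).

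In all, edgeR called 610 genes (3.38%), 302 higher and 308 lower, with 47 and 31 changed over 2-fold. With scaling by library size only the split was 448 higher and 170 lower, and the replicate block called 2012 genes, 914 higher and 1098 lower. The count was 297, 121 and 1104 without 5_FU replicate 2, 3 and 4, and 276, 138 and 152 without 5_FU_plus_EPS replicate 2, 3 and 4. It was 69 in a fit of the 6 libraries alone, 968 with DESeq2, and 0 by glmTreat against a 1.5-fold change, where 3570 genes had an unadjusted p under 0.05 without a minimum fold. The edgeR adjusted p of LGALS14 was 0.0518 and 0.0627 without 5_FU replicate 2 and 3, and 0.0518 and 0.101 without 5_FU_plus_EPS replicate 3 and 4. That of REG4 was 0.0787, 0.0781, 0.0966 and 0.123 in the same order, and that of COL5A1 0.0922 without 5_FU replicate 3 and 0.056, 0.0508 and 0.0538 without 5_FU_plus_EPS replicate 2, 3 and 4. SLC7A11 had 0.0568 without 5_FU replicate 3, and CEACAM5 0.064 without that library and 0.0586 without 5_FU_plus_EPS replicate 4 by edgeR.

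**Figure D2:**
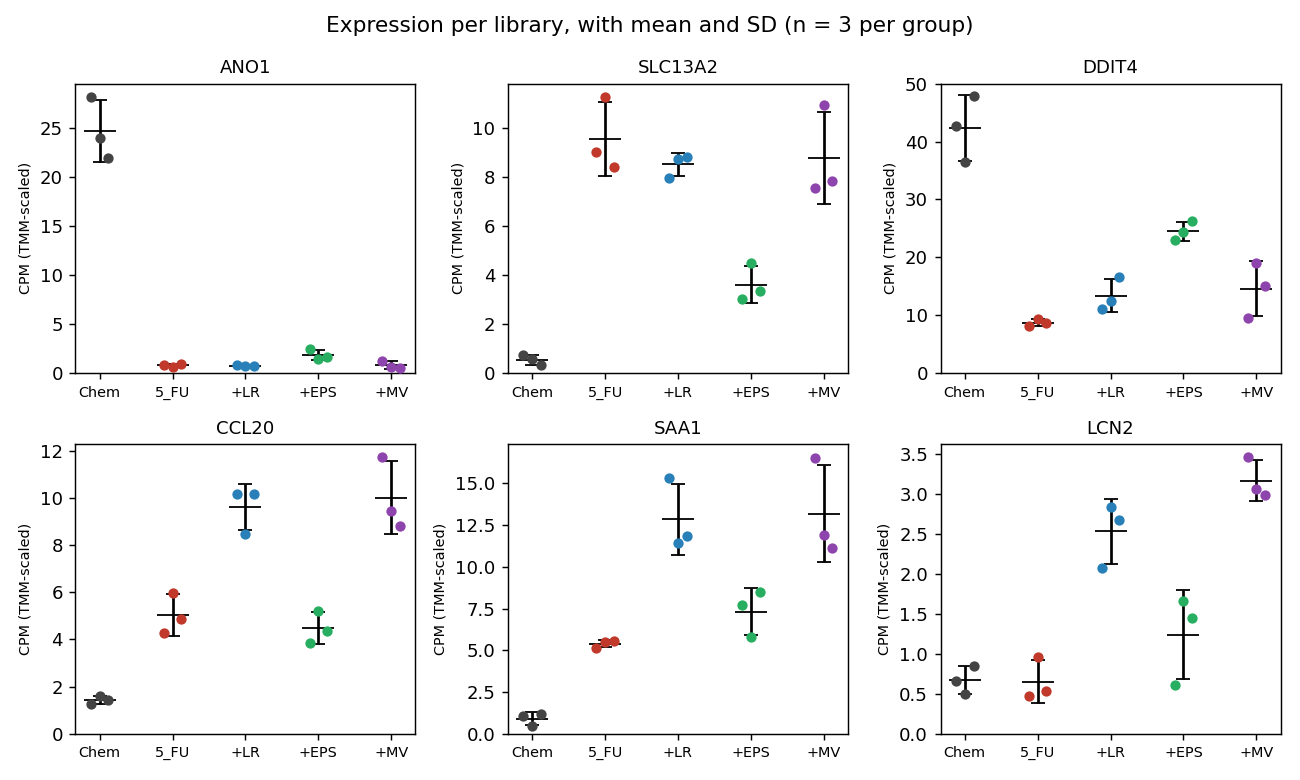
TMM-scaled CPM of 6 genes in each library (points), with the mean and SD of the 3 libraries of a group. DDIT4 is 24.5 CPM in 5_FU_plus_EPS against 8.68 CPM in 5_FU, SLC13A2 is 3.61 against 9.56 CPM, and CCL20 is 9.61 CPM in 5_FU_plus_LR and 10.0 CPM in 5_FU_plus_MV against 5.04 CPM in 5_FU.

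Of 24 genes of the unfolded protein and integrated stress response, 5 were higher and 1 lower (6 and 1 adjusted over the list alone), including SLC7A11 and CHAC1, which degrades glutathione (0.99 ± 0.20; edgeR adjusted p = 0.0128, and 0.0543 and 0.0513 without 5_FU_plus_EPS replicate 2 and 3). The list's camera adjusted p was 0.000554, and its adjusted p = 0.341 with an estimated correlation. Wound repair genes were higher in 4 of 31 (7 and 1 lower adjusted over the list alone), among them EGFR (0.42 ± 0.07) and the laminin gene LAMA3 (0.36 ± 0.06). Their camera adjusted p was 0.000554, and their adjusted p = 0.361 with an estimated correlation. Stem cell and WNT target genes were lower in 3 of 21 (6 lower and 1 higher adjusted over the list alone), among them LRIG1 (-0.39 ± 0.05) and RNF43 (-0.44 ± 0.07), which restrain growth factor and WNT signalling. The list's camera adjusted p was 0.000709, and its adjusted p = 0.361 with an estimated correlation. In the MHC class I list, TAP2, of the peptide transporter (0.37 ± 0.07), was among the 2 of 15 that passed (3 higher adjusted over the list alone; camera adjusted p = 0.00794, and adjusted p = 0.537 with an estimated correlation). Chemokine and NF-kB response genes had 1 of 27 higher, BIRC3 (0.72 ± 0.16; 2 adjusted over the list alone). BIRC3 had edgeR adjusted p values of 0.0641 and 0.106 without 5_FU replicate 2 and 3 and of 0.0994 and 0.0888 without 5_FU_plus_EPS replicate 3 and 4, and the list had a camera adjusted p of 0.0114 and an adjusted p = 0.361 with an estimated correlation.

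Among lists lower in 5_FU than in Chem, that of cholesterol biosynthesis had a median of -0.14 in 5_FU_plus_EPS minus 5_FU (camera adjusted p = 0.00332, and adjusted p = 0.361 with an estimated correlation). Replication-dependent histone genes had a median of -0.28, with 1 of 17 lower, H2BC12, uncertain as a near-identical copy (-0.41 ± 0.07; edgeR adjusted p = 0.00604; 1 adjusted over the list alone; camera adjusted p = 0.00817, and adjusted p = 0.341 with an estimated correlation). Cytosolic ribosomal proteins had a median of -0.04 (camera adjusted p = 0.283), which was 0.0067 with scaling by library size only. In the hypoxia and glycolysis list HK1 rose by 1.14 ± 0.19, with 1 higher, 1 lower and 24 of 26 not called (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00794, and adjusted p = 0.556 with an estimated correlation). Camera called 14 lists in all, of which 0 with an estimated correlation, and 8 without 5_FU_plus_EPS replicate 4. Of microbial sensing genes, NOX1 and REG4 were among the 3 of 20 that fell (3 adjusted over the list alone; camera adjusted p = 0.114, and 0.0442 with the replicate block). Paneth and tuft cell markers had 1 of 7 lower, the trypsinogen gene PRSS2, which has near-identical copies and is uncertain (-1.32 ± 0.24; edgeR adjusted p = 0.0586 without 5_FU_plus_EPS replicate 4; 1 adjusted over the list alone; camera adjusted p = 0.00794, and adjusted p = 0.341 with an estimated correlation). Among tight junction genes, MYLK (0.34 ± 0.09; edgeR adjusted p = 0.118 and 0.139 without 5_FU replicate 2 and 3, and 0.14 and 0.189 without 5_FU_plus_EPS replicate 3 and 4) was the 1 of 24 called (2 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.408), and the list's median of -0.04 was 4.33e-05 with scaling by library size only and its mean was 0.01, with camera's direction down. With the replicate block, members called higher and lower were 10 and 1 in the hypoxia and glycolysis list, 2 and 6 among tight junction genes, 8 and 1 in wound repair, 0 and 8 among stem cell and WNT target genes, 4 and 0 in the chemokine and in the MHC class I list, 0 and 6 in microbial sensing, 6 and 2 in the unfolded protein response list, and 0 and 2 among histone genes and among Paneth and tuft cell markers. In a fit of the 6 libraries alone, LGALS14, COL5A1, REG4, CHAC1, TAP2, MYLK, PRSS2 and H2BC12 were not called, with edgeR adjusted p values from 0.0507 for COL5A1 to 0.149 for MYLK. No panel gene passed. CLDN2 was 44.3 ± 7.26 CPM in 5_FU and 32.9 ± 3.86 CPM in 5_FU_plus_EPS (SD, n = 3; edgeR adjusted p = 0.0515, and 0.000264 with the replicate block), and OCLN was 177.3 ± 3.08 and 156.8 ± 5.92 CPM (edgeR adjusted p = 0.0693, and 0.0214 with the block). LGR5, CDKN1A, CLDN1 and TOP2A had edgeR adjusted p values of 0.12, 0.0802, 0.178 and 0.434, and of 0.000336, 0.0146, 0.0201 and 0.0368 with the block. CCL20 was 4.49 ± 0.684 CPM (edgeR adjusted p = 0.588).

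Exposed cells that received the component titled MV had 6 called genes, all higher than in 5_FU. PIGR, the receptor that carries immunoglobulins across epithelium, rose from 1.99 ± 0.774 to 6.58 ± 1.14 CPM (SD, n = 3), at 1.72 ± 0.29 (SE; edgeR adjusted p = 0.0455). SAA1 reached 13.2 ± 2.92 CPM (1.29 ± 0.19; edgeR adjusted p = 0.0193), the apolipoprotein gene APOA4 129.7 ± 43.7 CPM (1.24 ± 0.19; edgeR adjusted p = 0.0193) and CCL20 10.0 ± 1.55 CPM (0.98 ± 0.15; edgeR adjusted p = 0.0193). SAA2 (1.54 ± 0.20) and LCN2 (2.24 ± 0.30) completed the list.

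By edgeR 0 genes were lower, 1550 had an unadjusted p under 0.05, and limma-voom called 6 and DESeq2 43. The replicate block called 422, with 226 higher and 196 lower. Same-numbered libraries of 5_FU and 5_FU_plus_MV correlated at 0.329, 0.102 and 0.0852 for numbers 2, 3 and 4, the last under the bound of 0.1. Leaving out 5_FU replicate 2 gave 0 calls and 5_FU replicate 4 gave 2, while leaving out 5_FU_plus_MV replicate 2 gave 28. A fit of the 6 libraries alone and a test against a 1.5-fold change each called 0. Without 5_FU replicate 2 the edgeR adjusted p was 0.0769 for SAA2, 0.0809 for LCN2, 0.127 for SAA1, 0.148 for APOA4 and CCL20 and 0.177 for PIGR, and without 5_FU replicate 4 it was 0.0621 for LCN2, 0.0706 for SAA1 and APOA4 and 0.0731 for CCL20 and PIGR. Without 5_FU replicate 3 the edgeR adjusted p was 0.103 for SAA1 and APOA4 and 0.0827 for PIGR, which had 0.123 without 5_FU_plus_MV replicate 4.

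Chemokine and NF-kB response genes were higher in 4 of 27 (10 adjusted over the list alone), with a median of 0.33 and a camera adjusted p of 1.35e-19 (adjusted p = 0.00538 with an estimated correlation). Replication-dependent histone genes were the other list called with an estimated correlation, at a median of -0.24 and a camera adjusted p of 3.35e-06 (adjusted p = 0.0387 with an estimated correlation). Of their 17 members 0 were called by edgeR (1 lower adjusted over the list alone), and that with the smallest p was H2BC12 (-0.29 ± 0.07; edgeR adjusted p = 0.268, and 0.0491 by DESeq2). Cholesterol genes had a median of -0.18 and a camera adjusted p of 1.04e-10, with 0 of 22 called by edgeR (10 lower adjusted over the list alone; adjusted p = 0.0676 with an estimated correlation). MHC class I genes had a median of 0.21 and a camera adjusted p of 8.56e-09, with 0 of 15 called by edgeR (3 higher adjusted over the list alone; adjusted p = 0.203 with an estimated correlation). Brush border and enterocyte genes had 1 of 33 higher, APOA4 (3 adjusted over the list alone; camera adjusted p = 8.82e-05, and adjusted p = 0.33 with an estimated correlation). Camera called 13 lists, and 8 without 5_FU replicate 2. Of 19 panel genes CCL20 alone passed, while OCLN (-0.03 ± 0.05; edgeR adjusted p = 0.864) and CLDN1 (-0.02 ± 0.07; edgeR adjusted p = 0.95) did not, and the value of CLDN1 turned sign without 5_FU_plus_MV replicate 2 (0.00551) or 4 (0.00283), or 5_FU replicate 3 (0.00378) or 4 (0.0143).

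**Figure D3:**
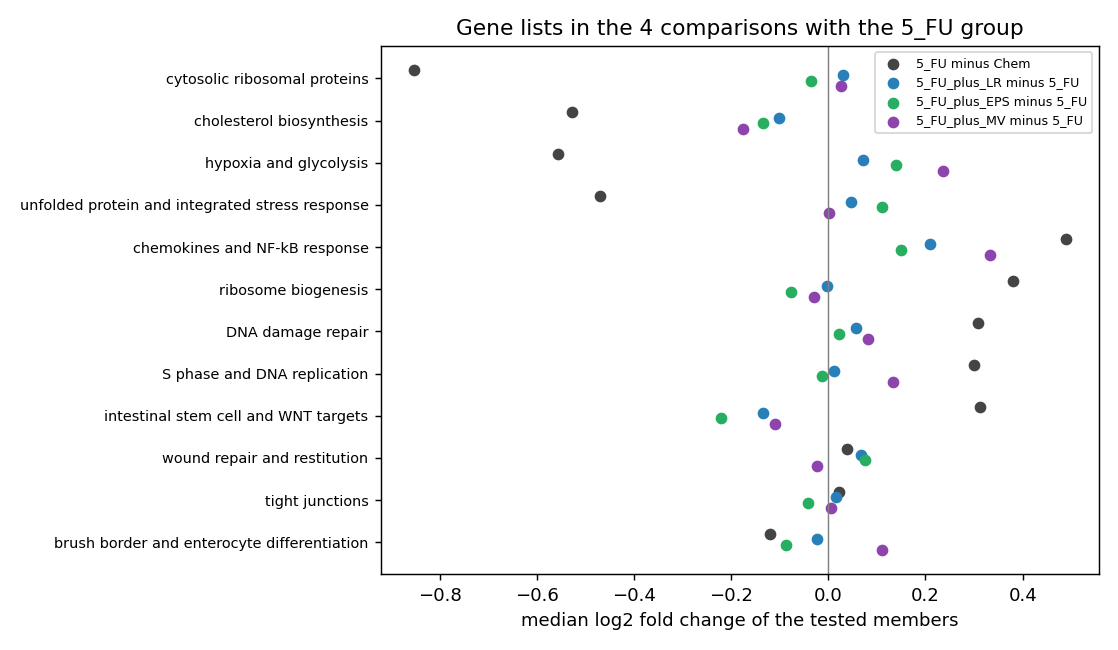
Median log2 fold change of the tested members of 12 gene lists (points) in the 4 comparisons with 5_FU, with 0 as a line. Cytosolic ribosomal proteins lie at -0.85 in 5_FU minus Chem, and chemokine and NF-kB response genes lie above 0 in every comparison drawn.

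The component groups were also tested against each other. The genes named here had at least 5 CPM in the higher group. CCL20 was lower in 5_FU_plus_EPS than in 5_FU_plus_LR, by a log2 fold change of -1.10 ± 0.15 (SE; edgeR adjusted p = 0.00465), as was SLC13A2 (-1.24 ± 0.19; edgeR adjusted p = 0.00522), while CACNG4, a calcium channel subunit (1.08 ± 0.16), LHPP (0.95 ± 0.12) and DDIT4 (0.89 ± 0.18) were higher. LINC02936 was lower (-0.84 ± 0.16), with edgeR adjusted p values of 0.071 and 0.102 without 5_FU_plus_LR replicate 2 and 3, and of 0.0867 and 0.111 without 5_FU_plus_EPS replicate 3 and 4. DDIT4 had 0.128 and 0.143 without 5_FU_plus_LR replicate 2 and 3, and 0.0639, 0.0889 and 0.149 without 5_FU_plus_EPS replicate 2, 3 and 4 by edgeR. In all 157 genes were called, 100 higher and 57 lower, and 849 with the replicate block. The count was 38, 44 and 61 without 5_FU_plus_LR replicate 2, 3 and 4, and 58, 50 and 27 without 5_FU_plus_EPS replicate 2, 3 and 4.

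Against 5_FU_plus_MV, 296 genes were called in 5_FU_plus_EPS, 188 higher and 108 lower, or 305 and 86 with scaling by library size only. COL5A1 (1.20 ± 0.27), SLC7A11 (1.13 ± 0.22) and CACNG4 (1.12 ± 0.16) were the largest rises at that level, and PIGR (-1.30 ± 0.28), SLC13A2 (-1.28 ± 0.19) and CCL20 (-1.16 ± 0.15; edgeR adjusted p = 0.00192) the largest falls. With 1 library left out, the edgeR adjusted p of PIGR was 0.0507 to 0.108 for each of the 6 libraries, that of COL5A1 0.0756 to 0.161 for each but 5_FU_plus_MV replicate 2, and that of SLC7A11 0.0716 to 0.0769 for 5_FU_plus_EPS replicate 2 and 5_FU_plus_MV replicate 3 and 4. The count was 30 and 88 without 5_FU_plus_MV replicate 3 and 4, and 85, 80 and 63 without 5_FU_plus_EPS replicate 2, 3 and 4. Between 5_FU_plus_LR and 5_FU_plus_MV, edgeR called 0 genes, as did limma-voom and DESeq2, and 670 genes had an unadjusted p under 0.05. Without a filter on low counts 57 were called.

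Set against Chem, edgeR called 9860 genes in 5_FU_plus_LR (5037 higher and 4823 lower), 8129 in 5_FU_plus_EPS (4098 higher and 4031 lower) and 9736 in 5_FU_plus_MV (4965 higher and 4771 lower). With scaling by library size only the split in 5_FU_plus_EPS was 5655 higher and 2968 lower, with the median of all genes shifted to 0.111. That scaling gave 6073 higher and 3980 lower in 5_FU_plus_LR, and 5838 higher and 4030 lower in 5_FU_plus_MV. Ribosomal protein mRNAs took 4.72 ± 0.0791% of counts in Chem, 2.63 ± 0.242% in 5_FU, 2.73 ± 0.114% in 5_FU_plus_LR, 2.62 ± 0.164% in 5_FU_plus_EPS and 2.70 ± 0.1% in 5_FU_plus_MV (SD, n = 3). Each exposed group differed from Chem at an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give.

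The comparisons with 5_FU share its 3 libraries, which alone makes their fold changes covary. Across genes, 5_FU_plus_EPS and Chem, each minus 5_FU, had a covariance of 0.134, against 0.0238 in 20 simulations of unchanged groups (r = 0.571 against 0.5). Called in both were 244 genes higher and 273 lower than in 5_FU, against 79.5 and 83.9 for independent lists, and 14 went opposite ways. For Chem with 5_FU_plus_MV the covariance was 0.0447 against 0.024 (r = 0.228 against 0.507), and for Chem with 5_FU_plus_LR 0.0332 against 0.024 (r = 0.184 against 0.509). Between component groups the covariance was 0.0429 against 0.0241 for 5_FU_plus_LR and 5_FU_plus_MV, 0.043 against 0.024 for 5_FU_plus_LR and 5_FU_plus_EPS, and 0.0459 against 0.024 for 5_FU_plus_EPS and 5_FU_plus_MV. In the same order 4, 1 and 0 genes were called higher in both by edgeR, against 0.00166, 0.0836 and 0.1 for independent lists. The 5_FU libraries were too few to split, so part of the excess may come from the shared libraries.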

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

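Scaling by library size only, and leaving out every library of number 2, were chosen after the data were seen. Counts of called genes and lists not printed here stayed within 1.5 times of those reported, and where a count moved further the cause was not tested, apart from fewer libraries in the fits that leave some out and the minimum fold of glmTreat. Of the 46 called genes named for Chem and 5_FU, 46 were called under each alternative but glmTreat (34 under it), as were 13 of 24 in 5_FU_plus_EPS (DESeq2 gave CYP24A1 no adjusted p) and 0 of 5 and 0 of 6 in 5_FU_plus_LR and 5_FU_plus_MV against 5_FU.

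Without a filter on low counts the calls were 116 for 5_FU_plus_LR, 1022 for 5_FU_plus_EPS and 391 for 5_FU_plus_MV against 5_FU, 427 for 5_FU_plus_EPS against 5_FU_plus_LR, 610 for 5_FU_plus_EPS against 5_FU_plus_MV and 57 for 5_FU_plus_LR against 5_FU_plus_MV. In the same order DESeq2 gave 8, 968, 43, 424 and 602, and leaving out all libraries of number 2 gave 9, 943, 193, 339, 886 and 3. Against a 1.5-fold change glmTreat called 2077 for Chem against 5_FU, 0 for each component group against 5_FU and for 5_FU_plus_EPS against the other component groups, and 2060, 981 and 2038 for 5_FU_plus_LR, 5_FU_plus_EPS and 5_FU_plus_MV against Chem. At an unadjusted p under 0.05, edgeR without a minimum fold gave 1218, 3570, 1550, 2575 and 2811 for the comparisons with 0. A fit of the 6 libraries alone called 2, 69 and 0 for 5_FU_plus_LR, 5_FU_plus_EPS and 5_FU_plus_MV against 5_FU, and limma-voom called 3 for 5_FU_plus_LR. With the replicate block the calls were 43, 2012 and 422 for the same comparisons, 849 for 5_FU_plus_EPS against 5_FU_plus_LR and 1168 against 5_FU_plus_MV. Among the lists, the block ended the call of senescence secretory factors in 5_FU_plus_LR against 5_FU (camera adjusted p = 0.0298, 0.0878 with the block, and 0.484 with an estimated correlation). It changed no other list call in the paired comparisons with 5_FU than that of microbial sensing genes. For pairs of groups whose numbers were not shown to pair, such as 5_FU_plus_MV with the others, the block is only a hint from the data. With 5_FU, however, 5_FU_plus_MV missed the bound of 0.1 in number 4 alone (0.0852).

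With 1 library left out, the calls ranged from 8604 to 9275 for Chem against 5_FU, 0 to 1 for 5_FU_plus_LR, 121 to 1104 for 5_FU_plus_EPS and 0 to 28 for 5_FU_plus_MV against 5_FU. They ranged from 27 to 61 for 5_FU_plus_EPS against 5_FU_plus_LR, 30 to 303 against 5_FU_plus_MV, and were 0 for each library left out between 5_FU_plus_LR and 5_FU_plus_MV, where edgeR gave 670 at an unadjusted p under 0.05 and limma-voom and DESeq2 gave 0. Against Chem they ranged from 8811 to 9056, 6813 to 7283 and 8637 to 9162. Lists called by camera ranged from 11 to 13 for Chem, 3 to 15 for 5_FU_plus_LR, 8 to 14 for 5_FU_plus_EPS and 8 to 16 for 5_FU_plus_MV against 5_FU, and with an estimated correlation 0, 1, 0 and 2 were called in place of 10, 11, 14 and 13.

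Of 144 list medians in the comparisons with 5_FU, 18 changed sign with RLE size factors or with library size only, all between -0.042 and 0.0278 and of lists that camera did not call. Of the named genes that were not called, an alternative called 1 of 3 for Chem, 2 of 4 for 5_FU_plus_LR, 6 of 7 for 5_FU_plus_EPS and 1 of 3 for 5_FU_plus_MV against 5_FU. Among named genes, values that changed sign belonged to genes that were not called. CDH1 was -0.0185 for Chem minus 5_FU with scaling by library size only. Over the 14 alternatives other than glmTreat, OCLN in 5_FU_plus_LR minus 5_FU ranged from -0.0693 to 0.00796 and CLDN1 from -0.0852 to 0.021. Both were highest without 5_FU_plus_LR replicate 2, and CLDN1 was 0.00226 without 5_FU replicate 4. Over the same alternatives, CLDN1 in 5_FU_plus_MV minus 5_FU ranged from -0.0731 to 0.0143, the highest without 5_FU replicate 4. It was 0.00551 and 0.00283 without 5_FU_plus_MV replicate 2 and 4 and 0.00378 without 5_FU replicate 3.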

Other observations

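The tests below were chosen after the result was seen for the 5_FU_plus_EPS pattern, for the inflammatory genes and for the scaling of ribosomal protein genes, while those of length and GC content, of pseudogenes and of other splits were set before.

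Libraries of 5_FU_plus_EPS lay toward Chem, but not in every gene list. On an axis from 5_FU_plus_MV (0) to Chem (1) built from 2203 genes without any 5_FU library, they stood at 0.239 ± 0.0179 and the 5_FU libraries at 0.0601 ± 0.0277 (SD, n = 3; exact permutation p = 0.1, the smallest possible), and of 493 genes called in 5_FU_plus_EPS against 5_FU and in Chem against 5_FU_plus_MV, 466 (94.5%) moved toward Chem. A 5_FU library standing apart and the scaling are argued against, since without 5_FU replicate 2 the groups stayed 0.168 apart while the other 5_FU libraries differed by 0.0144, and the smallest gap over 3 scalings was 0.128. For control cells or RNA mixed into the libraries, the direction of the genes did not decide: the median mixing fractions of genes higher and lower in Chem differed by -0.0775, with overlapping ranges over 9 library pairs (0.0423 to 0.162 and 0.067 to 0.214), and in the same-numbered pairs, the form that the pairing of 5_FU with 5_FU_plus_EPS calls for, they were 0.0836 and 0.173, 0.0935 and 0.162, and 0.112 and 0.144, without overlap under TMM and RLE but overlapping with library size only (-0.0419 at the smallest of 6 settings), while 12% of 601 genes lay over 3 standard errors from a single mixture, against 3.16% in 5_FU_plus_LR and 5.16% in 5_FU_plus_MV, short of a 3-fold margin that was also set after the result was seen. The summed CPM of ribosomal protein, cholesterol and histone genes, all higher in Chem, had median fractions of -0.00924, -0.196 and -0.39 from 5_FU. Genes higher in Chem had 0.0935, a median over genes rather than a fraction of a sum. In the same-numbered pairs each list lay wholly below those genes in all 6 settings of scaling and reference (by -0.0747 at the least). For these 3 lists this argues against mixing as the whole cause, on 3 pairs and in a test set with its TMM values known. The lists were picked after their values were seen. Left out were the hypoxia and glycolysis and the unfolded protein response lists, also called higher in Chem. Their medians in 5_FU_plus_EPS minus 5_FU were 0.139 and 0.111, toward Chem. On the lists used, 13 of 15 tests in 5 forms went the same way. The 5 forms reuse the same lists and the same 5_FU_plus_EPS libraries, so this count is no separate support. An earlier bound, each list wholly below against all 3 other exposed groups, was not met. Over the 9 library pairs with 5_FU, ribosomal protein genes overlapped the genes higher in Chem. Over those with 5_FU_plus_MV, cholesterol and histone genes did so, with median fractions of 0.0087 and 0.0031. Their median log2 fold changes against 5_FU were -0.102 and -0.146 in 5_FU_plus_LR and -0.175 and -0.238 in 5_FU_plus_MV. Falls from 5_FU in the cholesterol and histone lists were thus not particular to 5_FU_plus_EPS. Mixing beside another effect stays open, as does a partial return toward unexposed cells, a hypothesis.

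CCL20, SAA1, SAA2 and LCN2 were higher in 5_FU_plus_LR and 5_FU_plus_MV than in 5_FU. Handling shared by every group that received a component is argued against, as an effect acting alone, for CCL20 and SAA2. Both were lower in 5_FU_plus_EPS than in both groups (edgeR adjusted p at most 0.00465 for CCL20 and 0.0192 for SAA2, a near-identical copy of SAA1). However, 5_FU_plus_EPS lay toward Chem, where CCL20 had 124 counts in all against 432 in 5_FU, and SAA2 20 against 100. A rise from handling offset by that shift was not tested and stays open. For SAA1 and LCN2 handling stays open: against 5_FU_plus_MV the edgeR adjusted p was 0.03 and 0.0199, but against 5_FU_plus_LR it was 0.0518 and 0.0971, or 0.00214 and 0.0191 with the replicate block, which passes. Leukocyte RNA has little in its favour, with PTPRC at 0 CPM in 5_FU and 5_FU_plus_LR and 0.0238 CPM in 5_FU_plus_MV, where LCN2 went from 0.648 to 2.56 and 3.18 CPM, and with the leukocyte list not called (camera adjusted p = 0.548 and 0.154), but it is not excluded: the summed CPM of 14 markers was 12.3 and 8.53 CPM above 5_FU in these groups, over a bound of 1 CPM that was a poor one, since LCP1 led the sum and Chem stood 16.9 CPM above 5_FU with LCN2 at 0.637 CPM. A response to a bacterial component is a further candidate explanation that was not tested.

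Ribosomal protein mRNAs were lower in 5_FU than in Chem. Length or GC content of the longest annotated transcript is argued against as the whole cause. The 179 genes matched on these and on CPM had a median log2 fold change of -0.059 against -0.853. The median lengths so matched were 1846 bases for ribosomal protein genes and 2067 for the matched genes. The lengths of the transcripts actually expressed were not known, so a loss of short mRNAs was not tested and stays open. Scaling is argued against, since 32 of 32 were called lower under each of the other scalings. Reads passing to pseudogenes are argued against too, since the summed CPM of 1601 pseudogenes fell from 511.6 to 321.5, or -1.54% of what the genes lost. An effect of 5-FU on these mRNAs is a hypothesis, found and tested on the same data.

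For each comparison, the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 9676 genes for Chem, 5 for 5_FU_plus_LR, 610 for 5_FU_plus_EPS and 6 for 5_FU_plus_MV against 5_FU, 157 and 296 for 5_FU_plus_EPS against 5_FU_plus_LR and 5_FU_plus_MV, and 9860, 8129 and 9736 for the component groups against Chem in the same order. In each of these it was the 1 split of 10 with as many calls, and the highest other split called 0 by edgeR. Each other split puts libraries of both groups on each side, so a real difference widens the spread within groups and shrinks the contrast. Counts of 0 there are therefore no support for the calls. Between 5_FU_plus_LR and 5_FU_plus_MV all 10 splits called 0, where the real one had 670 genes at an unadjusted p under 0.05 by edgeR, and 0 by limma-voom and DESeq2.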
